A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

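CRAC libraries from Saccharomyces cerevisiae were compared, 1 from a strain with His-TEV-protein A tagged Bud22 and 1 from untagged W303. Per the labels' protocols, cells were grown in rich medium to an optical density (OD600) of 1.0, moved to synthetic medium without uracil and with 4-thiouracil for 4 h, and irradiated at 365 nm for 30 min. The groups follow the genotype labels. The growth text of the control names the tagged strain, whereas its genotype, title and source name say wild type, and this disagreement could not be resolved here.

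The deposited values are raw counts of reads per annotated feature, made with pyReadCounters from Counters version 1.2.1, per the file headers. Each feature has a sense count and an antisense count, and a column headed as a number of reads. From the values, that column holds the number of distinct read entries behind both strands: it exceeded the sum of the strand counts in 0 rows, and 1 entry stood for up to 114 reads in the Bud22 library and 65 in the control. This reading is inferred from the values, and how an entry was defined is not given in the sources used here. Copies that differ by a sequencing error would count as separate entries. The entry count was limited to the sense count where antisense entries made it larger. The aligner's version and settings, read trimming, removal of duplicates, the genome build and the annotation release are not given in the sources used here, so no coordinates are printed. Names of features are those of the files, and 2084 of 2635 features seen in either library matched a gene of the R64 reference table, which was used only for names and overlapping neighbours.

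A read was counted at every feature and every repeat copy it overlapped. The tRNA, 35S and 5S features summed over every copy came to 95.5% of the mapped reads that the header gives for the Bud22 library (188065) and 85.3% of those for the control (97270). With 1 copy per family they came to 17.1% and 24.7%. A family was the tRNA genes of 1 anticodon, with genes named otherwise (such as SUP53 or SUF16) placed by their known identity. The regions inside RDN37 were left out of the class shares with 1 copy. This grouping was revised after values from an earlier one, which kept the gene-named tRNAs apart and counted the regions, had been seen. The revision changed the tRNA values most. The mapped reads thus appear to count alignments, and no share of mapped over total reads is given. Intergenic regions name no gene and were left out of library totals. They held 15.8% of sense and 94.2% of antisense counts in the Bud22 library and 13.7% and 89.0% in the control.

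Shares of RNA classes, of 35S regions (over the reads of RDN37-2) and of snoRNAs were computed with exact Clopper-Pearson 95% intervals, and ratios of Bud22 over control with exact conditional binomial 95% intervals. Feature log2 ratios used a pseudocount of 0.5. A feature was called higher or lower with at least 10 counts over both libraries, a ratio of at least 2 either way and an interval excluding 1. A feature without reads in 1 library was given as a bound against a floor of 3 counts in that library, which is 0.00139% of the total with Bud22 and 0.00226% in the control. With 1 library per group there is no test, no SD and no p-value. Intervals and floors cover counting error only, since PCR copies of a molecule are not independent. With 36.5 reads per entry in the Bud22 library, a floor of 3 reads is less than the mean for 1 entry. Bounds of fold given as at least a value therefore hold for reads and not for molecules.

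Before the data were examined, 15 lists were fixed: rRNA features, 18S processing snoRNAs, box C/D and box H/ACA snoRNAs, snoRNAs with an 18S modification target, snoRNAs with only 25S targets, spliceosomal snRNAs, other stable RNAs, tRNAs, mitochondrial transcripts, and mRNAs of ribosomal proteins, small subunit biogenesis, glycolysis and translation elongation, the pyrimidine pathway, and heat shock and stress. The median log2 ratio of the measured members was placed among 10000 random lists of the same size matched on mean abundance in 10 bins, as a description of these libraries. Lists under 3 measured members got values only. The genes named were also fixed by rule: all rRNA features, the 5 18S processing snoRNAs and BUD22, the 10 features outside rRNA and tRNA with the highest Bud22 count, the 10 with the highest lower bound and the 10 with the lowest upper bound of the ratio, and in each list the 2 highest and the 2 lowest.

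Alternatives fixed beforehand were sense and antisense counts together, other denominators (mapped reads, totals without rRNA, without the most abundant feature or of tRNA only, and the median ratio set to 1), a pseudocount of 1, no minimum or at least 30 counts, a 99% interval, a 4-fold threshold and summed counts of a list. Distinct entries, 1 copy per repeated family, the cryptic unstable transcripts without CUT577, the 18S-target snoRNAs without SNR128, the box C/D snoRNAs without 3 members, and the shares of 35S regions and of snoRNA reads were chosen after seeing the data. Setting the median ratio to 1 moves every log2 ratio up by the median of the measured features, which is -0.93, and the class and feature ratios below are relative to the sense total over named features. The ratios of 35S regions and of snoRNA shares are relative to the 35S and the snoRNA total, and antisense ratios to the mapped reads of the header.

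The scripts were tested on simulated data. In 553 features drawn at the real abundances, with 200 changed 4-fold, 97% of raised and 64% of lowered features were called for the Bud22 over control comparison, and 4 of 351 unchanged ones. Of the 49 lowered features expected at 50 counts or more 98.0% were called. Here each read was drawn as an independent molecule, and the shift in the library total caused by the changes was known. The real libraries meet neither condition, so these rates are not the error rates of the calls below. A simulation with 36 copies per molecule in the Bud22 library and 4 in the control and no change, drawn 20 times, gave the chance calls quoted beside the call counts. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.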

Results

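RNA bound to Bud22 in budding yeast was measured by UV crosslinking and analysis of cDNA (CRAC), in which a protein carrying a His-TEV-protein A tag is purified under denaturing conditions after crosslinking and the attached RNA is sequenced. Bud22 is a nucleolar factor needed for making the small ribosomal subunit. The series holds 2 libraries, 1 from cells with tagged Bud22 and 1 from the untagged W303 wild type, which measures the background of the purification. Cells were labelled with the photoreactive uracil analogue 4-thiouracil for 4 h and irradiated at 365 nm for 30 min. Each group has 1 library, so no value below has a replicate error or a p-value, and every comparison is between these libraries and not between conditions.

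The Bud22 library held 317922 reads and the control 296925, and the sense counts over named features summed to 215982 and 132895. Distinct read entries summed over the same features came to 5920 in the Bud22 library and 37130 in the control. That is 36.5 reads per entry against 3.58. An entry, like a read, counts again at every repeat copy and overlapping feature, so the libraries hold fewer different entries than these sums. For tRNA the sums were 3027 and 8880, and 325 and 1052 with 1 copy per family. The 95% intervals given below are exact and cover counting error only. Since reads of 1 entry are not independent molecules, read-based intervals are too narrow, and ratios or numbers of distinct entries are given beside the main read ratios. Features with sense reads numbered 365 in the Bud22 library and 2183 in the control.

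The first question, given by the study's title, is which parts of the ribosomal RNA precursor were recovered with Bud22. Along the 35S pre-rRNA (RDN37), the 5′ external transcribed spacer (ETS1), which is removed from the precursor on the way to 18S rRNA, took 9.83% of the reads in the Bud22 library (interval 9.34 to 10.3) and 1.27% in the control (1.10 to 1.44). The ratio was 7.76 (6.72 to 9.0). By distinct entries the spacer held 56 of 558 in the Bud22 library and 124 of 4977 in the control, a ratio of 4.03 (2.88 to 5.57). The mature 18S sequence (RDN18) also took a higher share, at 40.6% against 23.3% of 35S reads, a ratio of 1.74 (1.67 to 1.81), and 1.21 by entries (1.04 to 1.41). This rise is relative to the 35S total only. Over all named features the RDN18 ratio was below 1, at 0.855 (0.821 to 0.891) by reads and 0.853 (0.729 to 0.993) by entries. The 25S sequence (RDN25), the large subunit's main rRNA, was lower, at 45.3% against 68.3%, with a ratio of 0.663 (0.643 to 0.684) and 0.779 by entries (0.688 to 0.879). The 18S to 25S quotient was therefore 0.896 with Bud22 and 0.342 in the control by reads, and 0.659 and 0.423 by entries.

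The remaining regions of the precursor gave no settled direction. Internal spacer 1 (ITS1), which lies between 18S and 5.8S, took 0.727% against 0.360% of 35S reads, a ratio of 2.02 (1.46 to 2.82). It rested on 4 entries in the Bud22 library, and its entry ratio was 1.05 (0.270 to 2.94). The 5.8S sequence (RDN58) was lower by reads, with a ratio of 0.675 (0.609 to 0.748), and had an entry ratio of 1.52 (0.960 to 2.31). Internal spacer 2 (ITS2) was lower by reads, with 34 reads against 175 and a ratio of 0.243 (0.163 to 0.353), and higher by entries, with 9 against 28 and a ratio of 2.87 (1.19 to 6.25).

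**Figure D1:**
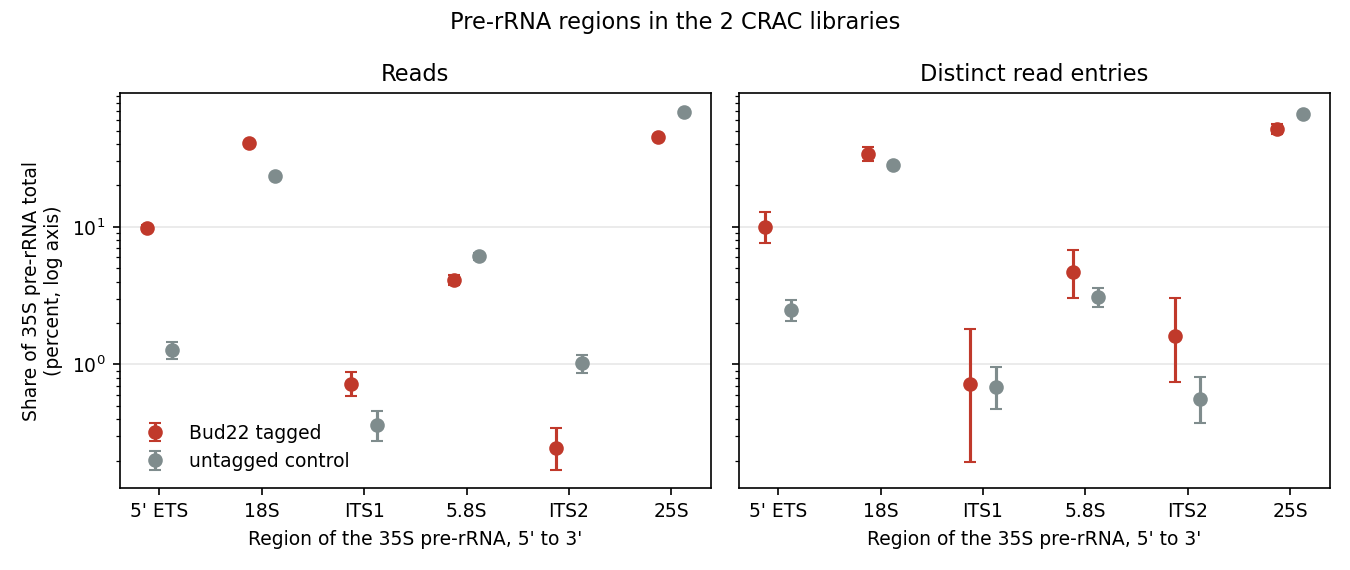
Share of the 35S pre-rRNA total (percent, log axis) in each region of the precursor, for reads on the left and distinct read entries on the right, in the Bud22 library (red) and the untagged control (grey); bars are exact 95% intervals for counting error. The 5′ external spacer lies higher in the Bud22 library in both panels, at 9.83% against 1.27% of reads and 10.04% against 2.49% of entries, while internal spacer 2 changes sides between the panels.

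Of the 5 snoRNAs that act in cleavage of the precursor to 18S rRNA, SNR30, SNR128 and SNR10 were higher with Bud22, and both U3 genes had no reads. The whole list took 54.8% of snoRNA reads in the Bud22 library (52.3 to 57.3) and 13.9% in the control (12.1 to 15.8), a ratio of 3.96 (3.38 to 4.64) and 2.19 by entries (1.40 to 3.34). SNR128 (U14) had 299 reads against 68, a ratio of shares of 4.09 (3.13 to 5.40), and 16 entries against 23, a ratio of 4.13 (2.04 to 8.17). SNR30 had 383 reads against 58, a ratio of 6.14 (4.65 to 8.24). Its 11 entries against 31 gave 2.11 (0.955 to 4.31), an interval that includes 1. SNR10 had 156 reads against 13, a ratio of 11.2 (6.34 to 21.4), and its 4 entries against 10 gave 2.38 (0.544 to 8.23). The U3 genes SNR17A and SNR17B, whose RNA pairs with the 5′ external spacer, had 39 and 19 reads in the control. Against a floor of 3 counts their share of all named features was at least 21.1-fold and 10.3-fold lower with Bud22. By entries, 0 against 20 for both genes together gave an upper bound of 1.203 for the ratio, so a lower share was not detectable at that depth. The list of 5 had a median log2 ratio over all named features of 1.43, at percentile 99.8 among random lists matched on abundance, with 3 members higher and 2 lower.

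By snoRNA class, box H/ACA snoRNAs, which guide pseudouridylation and here include SNR30 and SNR10, were higher by reads. Box C/D snoRNAs, which guide ribose methylation and here include SNR128 and U3, were lower. Box H/ACA snoRNAs took 57.9% of snoRNA reads against 9.49%, a ratio of 6.10 (5.08 to 7.36) and 1.98 by entries (1.24 to 3.07). Of 11 measured members 10 were higher and 1, SNR82, was lower, with a median log2 ratio of 2.49 at percentile 99.98. Most of these calls rest on 1 to 4 entries, as for SNR35 (31 reads against 0, 1 entry), SNR44 (29 against 0, 1 entry, inside RPS22B), SNR34 (56 against 1, 3 entries) and SNR37 (56 against 12, 2 entries). SNR35, SNR44 and SNR34 reached the minimum of 10 counts only through their Bud22 reads. At 36.5 reads per entry, 1 entry can both admit a member and make it higher. The count of higher members and the percentile are therefore no support for the class. With no minimum count the median was 1.68. Of 17 members seen in either library, 10 had reads with Bud22 and 15 in the control. Without SNR30 and SNR10 the class took 22.6% against 4.50%, a ratio of 5.03 (3.84 to 6.67), with an entry ratio of 1.80 (0.886 to 3.40). Box C/D snoRNAs took 42.1% against 90.4%, a ratio of 0.466 (0.423 to 0.513), and 0.727 by entries (0.499 to 1.03). SNR39B, SNR60 and SNR55, named after their values were seen, held 761 of the 1285 control reads and 90 of the 644 with Bud22. Without them the class took 36.2% against 36.8%, a ratio of 0.983 (0.871 to 1.11), and 0.836 by entries (0.546 to 1.24), both intervals including 1. Of 21 measured members 3 were higher and 12 lower, with a median of -1.52 at percentile 31.9. SNR13 (0 reads against 44) was at least 23.8-fold lower, and SNR41 (0 against 30) and SNR77 (0 against 22) were at least 16.3-fold and 11.9-fold lower. These 3 had 0 entries against 19, 13 and 11, with upper bounds of 1.34, 2.06 and 2.499 for the entry ratio, and were not lower by entries. SNR51 (33 against 1) and SNR54 (24 against 3) were higher, on 1 entry each. By entries 1 box C/D snoRNA of 11 measured was lower (SNR39B) and 1 higher (SNR128), and of 4 measured box H/ACA snoRNAs 1 was higher (SNR30).

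Sorted by the rRNA they modify, the whole list of snoRNAs with an 18S target took more of the snoRNA reads with Bud22. The whole list with only 25S targets took less. Both read directions rested on few members. The 18S-target list took 33.1% against 25.1% of snoRNA reads, a ratio of 1.32 (1.15 to 1.51), and 1.48 by entries (0.936 to 2.28), an interval that includes 1. Without SNR128 it took 13.5% against 20.3%, a ratio of 0.666 (0.555 to 0.799), and 0.768 by entries (0.370 to 1.45). Of the reads then left, SNR55 held 36 of 207 with Bud22 and 149 of 289 in the control. Without SNR55 as well, the share of snoRNA reads would not be lower. By entries SNR55 held 1 of 11 with Bud22 and 16 of 85 in the control, and the rest stayed slightly lower. No interval was computed for that rest. The 25S-only list took 29.6% against 64.9%, a ratio of 0.456 (0.407 to 0.511), and 0.614 by entries (0.372 to 0.964). SNR39B (37 reads against 314) and SNR60 (17 against 298), picked after their values were seen, held most of its 923 control reads. Without them its share of snoRNA reads would not be lower. Of its 21 entries with Bud22 and 203 in the control, SNR39B held 1 and 38 and SNR60 5 and 34. The rest stayed lower by entries, again without a computed interval. Over all named features the ratios of the whole 18S-target and 25S-only lists were 0.872 (0.760 to 1.001) and 0.302 (0.269 to 0.338) by reads. By entries they were 1.57 (0.988 to 2.41) and 0.649 (0.393 to 1.02). The single members went both ways. Of 13 measured snoRNAs with an 18S target 5 were higher and 5 lower, with a median log2 ratio of 0.41 at percentile 92.9. Of 14 with only 25S targets 6 were higher and 6 lower, with a median of 0.26 at percentile 93.9. Both medians fell below 0 with totals without rRNA, to -0.25 and -0.41, and with no minimum count, to -2.51 and -3.51. By entries 1 of 5 measured 18S-target snoRNAs was higher (SNR128), and 1 of 7 measured 25S-only snoRNAs was lower (SNR39B).

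**Figure D2:**
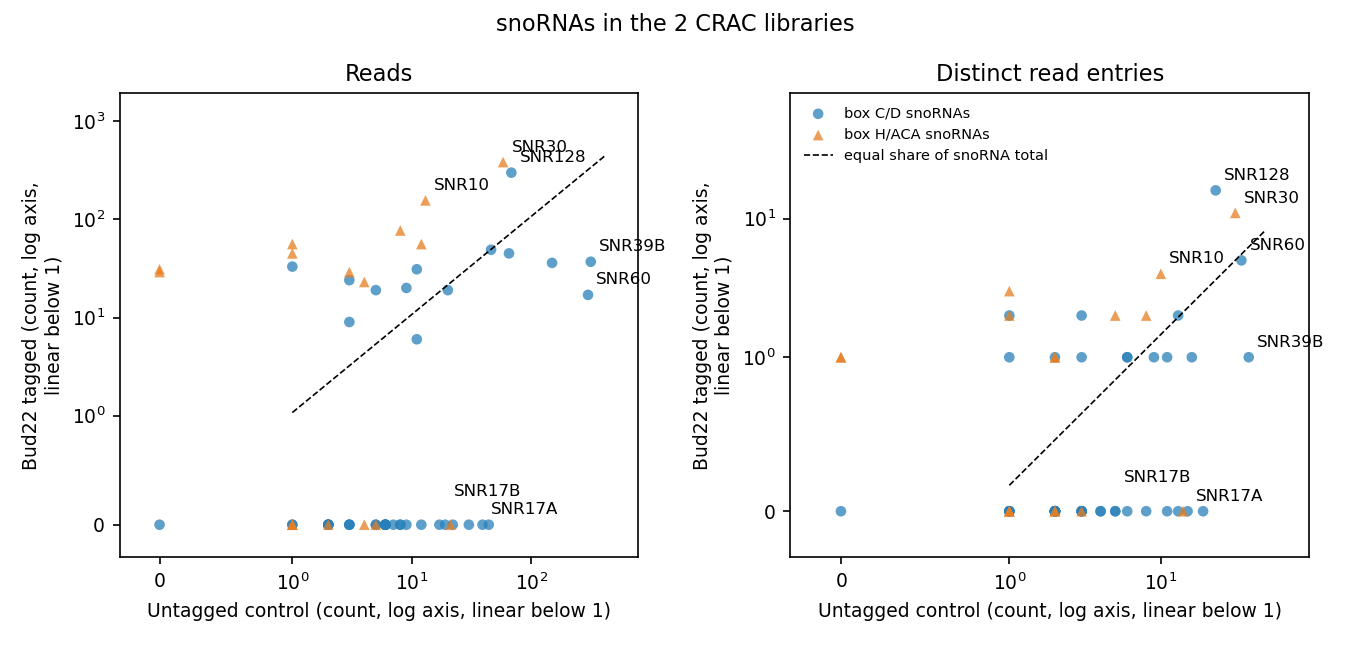
Counts of each snoRNA in the Bud22 library (vertical) against the untagged control (horizontal), both on log axes that are linear below 1, for reads on the left and distinct read entries on the right. Circles are box C/D and triangles box H/ACA snoRNAs, and the dashed line marks equal shares of the snoRNA total; SNR30, SNR128 and SNR10 lie above it in both panels and the U3 genes SNR17A and SNR17B lie at 0 with Bud22.

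Across RNA classes, tRNA was higher with Bud22, and rRNA and protein-coding RNA were lower. tRNA took 68.0% of the sense reads over named features against 33.4% in the control, a ratio of 2.04 (2.01 to 2.06) and 2.14 by entries (2.05 to 2.23). rRNA took 27.9% against 54.4%, a ratio of 0.512 (0.506 to 0.517) and 0.707 by entries (0.677 to 0.737). Protein-coding features took 3.19% against 10.7%, with a ratio of 0.297 (0.288 to 0.305) and 0.384 by entries (0.345 to 0.426). The snoRNA class took 0.708% against 1.07%, a ratio of 0.662 (0.615 to 0.712), while its entry ratio was 1.06 (0.798 to 1.38). A read counts at every repeat copy it overlaps, and with 1 copy per repeated family tRNA took 42.4% against 15.2%, rRNA 35.9% against 44.9% and protein-coding features 16.7% against 35.3%. YLR154C-G, which lies within 25S, held 3439 of those 6881 protein-coding reads with Bud22 and 5019 of 14276 in the control. With totals without rRNA the ratio was 1.29 for tRNA and 0.187 for protein-coding features.

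**Figure D3:**
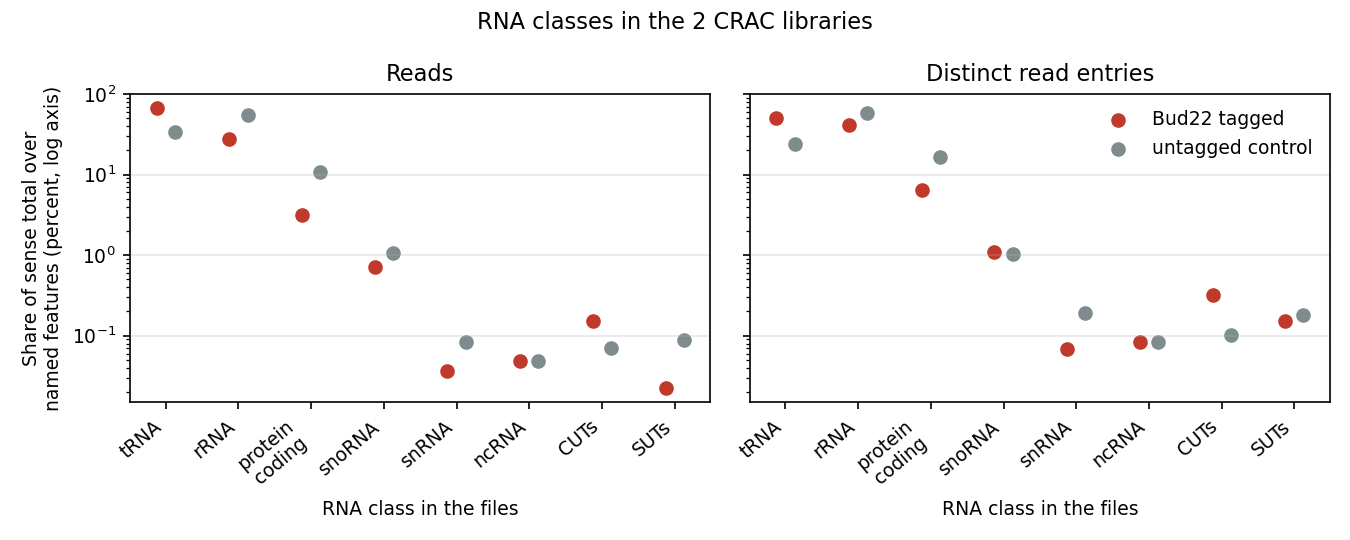
Share of the sense total over named features (percent, log axis) taken by each RNA class in the Bud22 library (red) and the untagged control (grey), for reads on the left and distinct read entries on the right. tRNA lies higher in the Bud22 library (68.0% against 33.4% of reads) and protein-coding RNA lower (3.19% against 10.7%) in both panels, while the snoRNA class changes sides.

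The 13 copies of tI(AAU), an isoleucine tRNA, and the 8 SUP genes for tyrosine tRNA together took 78.0% of tRNA reads in the Bud22 library and 52.8% in the control, a ratio over all named features of 3.005 (2.96 to 3.05) and 4.02 by entries (3.79 to 4.27). Taken apart, the ratio was 2.55 (2.52 to 2.59) for tI(AAU) and 12.2 (11.5 to 13.0) for the SUP genes. By entries it was 3.34 and 10.3. The same reads and entries count at several copies, so all these intervals are too narrow. The other tRNA features had a ratio of 0.951 (0.934 to 0.967), and 1.28 by entries (1.21 to 1.36), and 35 of them were higher by reads and 29 by entries. These 2 sets were singled out after their values were seen, which by itself lowers the ratio of the rest. The tyrosine tRNA gene SUP6 had 2721 reads against 136, a ratio of 12.3 (10.4 to 14.7), and 57 entries against 33, a ratio of 10.8 (6.94 to 17.2). SUP5, SUP8 and SUP11 had the same reads. Leucine tRNA tL(UAG)J had 0 reads against 81, at least 43.9-fold lower, on 19 entries in the control, and was not lower by entries over all named features. Relative to the total of tRNA families, each counted by its most counted copy, the upper bound of the tL(UAG) entry ratio was 0.694. Of 249 measured tRNA features 56 were higher and 101 lower, with a median log2 ratio of -0.32 at percentile 27.5, which turned to 0.61 with the median ratio over all measured features set to 1. The median and the summed reads differ in sign. The list makes up 249 of the 494 measured features, so the random lists are largely drawn from its own members. Copies also share reads, so the percentile cannot place the list. By entries 50 were higher and 13 lower of 226.

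Of 494 features with at least 10 reads over both libraries, 117 were at least 2-fold higher with Bud22 with an interval excluding 1, and 244 were lower, of which 159 had no read in the Bud22 library. The split was 62 higher and 265 lower with totals without rRNA, and 161 higher and 216 lower with the median ratio set to 1. By entries 60 were higher and 43 lower of 342 measured, and 40 and 42 passed in both counts. In simulated libraries with no difference but 36 and 4 copies per molecule, a median of 180 features were called higher and 133.5 lower by reads. That setting gave every feature the same copies, whereas reads per entry with Bud22 were 48.5 for tRNA and 18.1 for protein-coding features. It also drew repeat copies and overlapping features separately. Copies alone can thus give many calls either way, but the simulated numbers cannot be set directly beside those seen. Protein-coding features made up 36 of the higher and 115 of the lower calls among 174 measured, and 22 of the 36 rested on at most 2 entries. The features in the rRNA class were 4 higher and 9 lower of 23, with a median of -0.36 at percentile 0.065. That median turned to 0.57 with the median ratio over all measured features set to 1. These features are not separate RNAs, since repeat copies share reads and RDN37 contains its regions. The higher calls were ETS1 and NTS2, each at both copies, and the lower included the mitochondrial 15S_RRNA and 21S_RRNA. The percentile takes each feature as a separate member, so its low value cannot be read as that of 23 separate RNAs. ETS1 was among the higher by reads and by entries (3.82, interval 3.31 to 4.42, and 2.83, 2.03 to 3.91), and so was spacer NTS2 by reads (37 against 4, with 2 entries for both strands together in the Bud22 library). The 5S genes were neither, with 908 reads against 711 at RDN5-1.

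Among messenger RNAs, abundant housekeeping and stress transcripts present in the control were mostly without reads in the Bud22 library. This held for protein-coding features in general and is not particular to these lists. Those with sense reads numbered 106 with Bud22 and 1723 in the control, and 115 of 174 measured were lower. The entry ratio of the whole class was 0.384 (0.345 to 0.426). None of the 7 measured heat shock and stress mRNAs had a read with Bud22, and all 7 were lower by reads. The chaperone genes SSB1 (0 reads against 37) and SSA1 (0 against 32) were at least 20.04-fold and 17.3-fold lower, and HSP82 (0 against 21) at least 11.4-fold. The list's median log2 ratio was -6.43, at percentile 41.6, and -3.82 with genes without reads at their bound. By entries 0 of 5 measured members passed singly, and 0 against 93 entries for the whole list gave an upper bound of 0.254. Of 13 measured mRNAs of glycolysis and translation elongation 9 were lower and none higher, with a median of -6.13 (-3.51 at the bound) at percentile 10.2. By entries 1 of 11 was lower, and the whole list had a ratio of 0.284 (0.134 to 0.532). Examples are the pyruvate kinase gene CDC19 (0 against 99, at least 53.6-fold lower by reads, on 9 control entries) and the glyceraldehyde-3-phosphate dehydrogenase gene TDH3 (0 against 53, at least 28.7-fold lower by reads, on 27 entries, also lower by entries). The upper bounds of their entry ratios were 3.18 for CDC19 and 0.918 for TDH3. TEF1 and TEF2, near-identical genes for elongation factor EF-1 alpha, shared 151 reads in the Bud22 library against 57 and 59, ratios of 1.63 and 1.57, and each had an entry ratio of 1.05 (0.264 to 3.04).

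Ribosomal protein mRNAs had 8 lower and 2 higher of 11 measured, with a median log2 ratio of -5.09 (-2.44 at the bound) at percentile 53.8. By entries 1 was higher and 0 lower of 2 measured, the first being RPL18B (6 entries against 4, named after its values were seen). The whole list had an entry ratio of 0.396 (0.213 to 0.678), close to 0.384 for all protein-coding features. By reads RPL8A (0 against 20) was at least 10.8-fold lower and RPP0 (0 against 12) at least 6.50-fold lower. They had 7 and 5 control entries, with upper bounds of 4.35 and 6.84 for the entry ratio, so neither was lower by entries. RPL8B (32 reads against 9) had a ratio of 2.19 (1.02 to 5.21). The other higher member, RPS22B (29 against 6), carries the snoRNA SNR44, whose 29 reads are the same number. Of 3 measured small subunit biogenesis mRNAs 2 were higher, BMS1 (40 reads against 1, 2 entries) and NOP1 (39 against 3, 1 entry), and UTP6 had 12 against 14. Their median was 2.80 at percentile 90.9, and 0 of 1 measured passed by entries. BMS1 and NOP1 reached the minimum of 10 counts only through their Bud22 reads, so this percentile gives no support. The whole list had 92 reads against 76, a ratio of 0.745 (0.544 to 1.02), and 1.09 by entries (0.445 to 2.33), so its sum and its median differ in direction by reads. No pyrimidine pathway mRNA reached 10 reads, with 0 against 17 for the whole list.

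Other stable RNAs split by gene. Of 5 measured spliceosomal snRNAs, 3 were lower and 1 higher, with a median of -2.58 at percentile 19.0. The U5 forms SNR7-L (0 reads against 15) and SNR7-S (0 against 14) overlap, so that these calls are not separate, and were at least 8.13-fold and 7.58-fold lower. Their entry ratios had upper bounds of 2.26 and 2.499, and by entries 0 of 4 measured snRNAs were lower. LSR1 (U2) had 43 reads against 51, and SNR19 (U1) had 29 against 3 on 1 entry. SCR1, the RNA of the signal recognition particle, had 105 reads against 47, a ratio of 1.37 (0.966 to 1.98). RPR1, the RNA of RNase P, had 0 against 10, at least 5.42-fold lower by reads, on 2 control entries. The upper bound of its entry ratio was 33.4, so it was not lower by entries. With 2 measured members this list has no percentile.

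The features with the highest lower bounds outside tRNA had sense reads in the Bud22 library only. CUT577, a cryptic unstable transcript, had 178 reads against 0, at least 36.5-fold higher, on 4 entries, and CUT812 had 72 against 0 on 1 entry. QRI7 had 108 against 0 on 8 entries, at least 22.2-fold higher, and MNR2 had 102 against 0 on 7 entries, at least 20.9-fold higher. MNR2 also had 5 antisense reads in the control and 20 with Bud22, and its log2 ratio of 6.98 became 3.82 with both strands. Its 7 entries cover both strands. TRP4 (95 against 0) and PAM1 (92 against 0) rested on 2 entries each. YDL206W, among the most counted, had 117 reads against 6 and 12 entries against 4, with ratios of 12 (5.35 to 33.4) and 18.8 (5.70 to 80.0). Among the lowest upper bounds were 4 Ty retrotransposon reading frames, which share sequence with other copies of the element. YDR098C-B (0 against 86 reads, 49 entries), YDR210C-D (0 against 82, 46 entries), YOR142W-B (0 against 74, 45 entries) and YAR009C (0 against 74, 35 entries) were each at least 40.1-fold lower by reads. They were also lower by entries, with upper bounds of 0.490, 0.524, 0.536 and 0.697 in the same order, a much smaller fold. YDR098C-B, YDR210C-D and YOR142W-B each had 21 antisense reads in the control. Their entries cover both strands, so their bounds may be too low. URM1 (0 against 91, 21 entries) and SCM4 (0 against 80, 2 entries) were at least 49.3-fold and 43.3-fold lower by reads and not by entries. YGL088W repeats the counts of SNR10, which it overlaps, and YLR154C-G (3439 against 5019) lies within 25S.

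Reads of the BUD22 gene itself numbered 0 in both libraries. Were reads independent, this would allow a share of up to 0.00139% in the Bud22 library and 0.00226% in the control. With 36.5 reads per entry in the Bud22 library and 3.58 in the control, the limits in molecules are higher. A tag on the protein does not set the level of its mRNA, so this value does not check the labels.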

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

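All tests in this part were chosen after the result was seen. Antisense counts, which the comparisons do not use, stood above the control in intergenic regions. They numbered 177360 in the Bud22 library and 86484 in the control, which is 94.3% against 88.9% of the header's mapped reads, a ratio of 1.06 with a lower bound of 1.05. That total appears to count alignments and not reads. Sense counts of tRNA, 35S and 5S features over every copy came to 95.5% of it with Bud22 and 85.3% in the control. If an alignment counts once in each sum, both sums must largely hold the same alignments. Most intergenic antisense counts would then be alignments already counted as sense at those features. The ratio of 1.06 is therefore not read as a separate signal. Over the same total, antisense reads went the other way in protein-coding features (0.556), cryptic unstable transcripts (0.160) and stable unannotated transcripts (0.0752). Antisense reads over the rDNA spacer copies NTS2-1 and NTS2-2 numbered 35 with Bud22 and 0 in the control at each copy, and the same reads count at both. NTS2-1 has 2 entries for its 37 sense and 35 antisense reads together. No explanation was tested for either.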

How the results depend on the processing

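Distinct entries, 1 copy per repeated family, cryptic unstable transcripts without CUT577, snoRNA groups without single members, and all named features as the denominator of snoRNAs were chosen after seeing the data; the other alternatives were planned. The cause of each change was not tested. Directions of called values turned under these settings. The snoRNA class ratio became 1.06 by entries and 1.05 with 1 copy per family, and that of cryptic unstable transcripts 0.969 without CUT577. The ratio of snoRNAs with an 18S target became 0.872 over all named features, and 0.666 by reads and 0.768 by entries without SNR128. With the median ratio set to 1 the list medians became 0.57 for rRNA and 0.61 for tRNAs, and tRNAs also turned with summed counts (1.03) and entries (0.15). By entries the 35S share ratios became 1.52 for 5.8S and 2.87 for internal spacer 2, and the log2 ratios 0.33 for RPR1 and SCM4, 0.62 for ITS2-1, 1.06 for ITS2-2 and 0.11 for RDN58-2. RPR1 and SCM4 have 0 entries with Bud22, so their sign comes from the pseudocount.

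Class ratios kept their direction but moved as follows. rRNA was 0.527 with both strands, 0.430 over mapped reads, 0.481 without the most abundant feature, 0.707 by entries and 0.800 with 1 copy. tRNA was 2.09, 1.71, 1.89, 2.14 and 2.79 in the same order, and 1.29 without rRNA. Protein-coding was 0.459, 0.249, 0.276, 0.384 and 0.472, and 0.187 without rRNA. Cryptic unstable transcripts were 3.14 by entries. snoRNA was 0.556 over mapped reads, 0.418 without rRNA and 0.615 without the most abundant feature. Higher features numbered 62 without rRNA, 69 at 4-fold and 60 by entries. Lower features numbered 735 with no minimum, 137 at 30 counts or more, 43 by entries and 136 with 1 copy. Medians moved without rRNA to -0.98 for tRNAs, -5.76 for ribosomal protein and -7.09 for heat shock mRNAs. They moved to -0.0451 for tRNAs with 1 copy (a value that depends on how gene-named tRNAs are grouped), -3.02 for small subunit biogenesis mRNAs with no minimum (from 2.80, a list without a settled direction, and -0.42 with summed counts) and -2.21 for heat shock mRNAs by entries. The medians of 18S-target and 25S-only snoRNAs, whose intervals include 0, changed sign without rRNA (-0.25 and -0.41), with no minimum (-2.51 and -3.51) and with summed counts (-0.20 and -1.73). By entries the 35S ratios were 4.03 for the 5′ external spacer, 1.21 for 18S, 1.05 for internal spacer 1 and 0.779 for 25S. Among snoRNAs they were 2.11 for SNR30, 2.38 for SNR10, 2.88 for these and SNR128 together (5.61 by reads, 3 members singled out after their values were seen), 2.19 for the whole 18S processing list, 0.614 for 25S-only targets, 1.98 for box H/ACA and 0.727 for box C/D. Without SNR39B, SNR60 and SNR55 box C/D was 0.983 by reads and 0.836 by entries. Over all named features they were 4.06 for SNR30, 2.71 for SNR128, 3.71 for the 3 together, 2.62 for the whole list, 0.302 for 25S-only targets, 4.03 for box H/ACA and 0.308 for box C/D.

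Of the log2 ratios of 82 named features under all alternatives, 345 stayed within their interval and 119 moved, and 5 of called features turned, as given above. A further 17 values of 14 features without a call changed sign. UTP6 went from -0.91 to 1.17 by entries, SCR1 from 0.45 to -0.21 without rRNA and -0.58 over tRNA, and TEF1 and TEF2 to -0.33 and -0.38 over tRNA. RDN18 went from -0.23 to 0.70, and RDN5-1 from -0.35 to 0.58, with the median ratio set to 1. The low number of entries in the Bud22 library limits every call. No paired analysis was possible because each group has 1 library.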

Other observations

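Mitochondrial transcripts were lower with Bud22. The mitochondrial small subunit rRNA (15S_RRNA) had 0 reads against 52 in the control, at least 28.2-fold lower, on 26 control entries, with an upper bound of 0.956 for the entry ratio. The large subunit rRNA (21S_RRNA) had 138 reads against 181, a ratio of 0.469 (0.373 to 0.589), and 5 entries against 74, a ratio of 0.424 (0.134 to 1.03). These were the 2 measured members of the list. Over all 8 listed members, the entries gave a ratio of 0.290 (0.0924 to 0.699).

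Cryptic unstable transcripts as a class had 326 reads against 94, a ratio of 2.13 (1.69 to 2.71), and 19 entries against 38, a ratio of 3.14 (1.71 to 5.58). CUT577 gave 178 of these reads, and without it the ratio was 0.969 (0.743 to 1.27) by reads and 2.48 (1.27 to 4.61) by entries. They came from 5 features in the Bud22 library and 23 in the control. Stable unannotated transcripts had 48 reads against 117, a ratio of 0.252 (0.177 to 0.356), with an entry ratio of 0.830 (0.364 to 1.67). Counting each tRNA family by its most counted copy, the tyrosine SUP family had 2721 reads against 139 and a ratio among families of 6.86 (5.79 to 8.20), and 5.27 by entries (3.40 to 8.28). The isoleucine family tI(AAU) had 11132 against 3332 and a ratio of 1.17 (1.13 to 1.22), and 1.70 by entries (1.35 to 2.13). The alanine family tA(AGC) had 842 against 208 and ratios of 1.42 and 1.88 (1.10 to 3.15 by entries). The cysteine family tC(GCA) had 66 against 256 and a ratio of 0.0904, with 0.288 by entries (0.0752 to 0.789).

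All tests in the paragraphs that follow were chosen after the result was seen, and they take distinct entries as separate molecules, which no header states. Copies that differ by a sequencing error would count as new entries, so the tests bear on exact copies only.

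The first pattern is the higher share of the 5′ external spacer. Exact PCR copies as the whole cause would leave an entry ratio that includes 1, and it was 4.03 (2.88 to 5.57). A lower background of mature rRNA would raise all spacers of the precursor alike. The odds ratio of external over internal spacer entries was 3.82 (1.27 to 15.5) for internal spacer 1, 1.40 (0.594 to 3.61) for internal spacer 2 and 2.15 (1.06 to 4.61) for both. The pooled interval lies just above 1 and that for internal spacer 2 includes 1 on 9 entries, so this explanation stays open, as do copies with errors and batch differences. Contact of Bud22 with the 5′ external spacer is a hypothesis that was not separated from these.

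The second pattern is the higher share of the 18S processing snoRNAs together with the lack of U3. Exact PCR copies alone do not account for the list, with an entry ratio of 2.19 (1.40 to 3.34), or for SNR128, at 4.13 (2.04 to 8.17). For SNR30 the entry ratio among snoRNAs was 2.11 (0.955 to 4.31), below the read ratio's interval and including 1, as exact copies would give, while over all named features it was 2.23 (1.01 to 4.55). For SNR10, at 2.38 (0.544 to 8.23), 4 entries leave the question open. At the control's share, 3.37 U3 entries would be expected with Bud22, and the upper bound of 1.203 leaves open whether U3 is depleted or too few molecules were sampled.

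The third pattern is the lower protein-coding share. Exact PCR copies alone would leave the entry ratio at 1, and it was 0.384 (0.345 to 0.426). Removing tRNA, whose reads fill the Bud22 library, gave 0.598 (0.538 to 0.663), and removing also the reading frames that overlap the 25S gene gave 0.468 (0.407 to 0.536). A purification with less nonspecific mRNA is a candidate explanation and remains untested, as does a difference between single libraries that has nothing to do with the tag.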
